A study of Mus musculus with 2 samples.

How the data were processed

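Single-cell RNA was measured in germ cells of mouse embryos at embryonic day 15.5 (E15.5) from strain 129Sv/ImJChr19MOLF/Ei, which the labels describe as tumor-susceptible. Per the labels, germ cells were enriched by flow sorting from a pool of 4 mice and divided by a NANOS2-RFP reporter, a red fluorescent protein that marks cells using the male germ cell gene Nanos2. Each sorted fraction gave 1 library on the 10x Genomics Chromium platform, so the design holds 1 RFP-positive and 1 RFP-negative library and no replicates.

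The authors deposited raw counts, that is whole numbers of unique molecular identifiers (UMIs) per gene and barcode, as a matrix of called barcodes and a matrix of all barcodes for each library. Per the file headers, the matrices were written by Cell Ranger 3.1.0. The submitters' processing notes name Cell Ranger, the mouse build mm10 and Seurat 3.1.1. No output of Seurat was used here. Both matrices hold the same 31053 genes, of which 31011 (99.9%) had their identifier in GENCODE M21 for mm10, the annotation used for positions. Gene identity followed the identifier, since 35 symbols belong to more than 1 identifier. The gene set has no feature for RFP, so reporter RNA was not measured, and reporter protein was known only from the sort. Reads that match near-identical copies are not assigned by Cell Ranger, so levels of genes with such copies are uncertain.

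The lists of genes and markers, the filters, the thresholds, the choice of genes to name and most alternatives were set before the data were examined. Cells were called barcodes with at least 1000 UMIs, at least 500 detected genes and at most 10% of UMIs from mitochondrially encoded genes. Doublets were scored in each library with Scrublet as run in scanpy 1.11.5, with its automatic threshold. The caller marked 0 of 14666 RFP-positive cells and 5 of 2413 RFP-negative cells (0.207%) at thresholds of 0.673 and 0.434, under the 0.5% of cells set as the minimum for a working caller, so no cell was removed. Cells of both libraries were scaled to 10000 UMIs, put on a log scale and clustered together on 2000 variable genes, 30 components and 15 neighbours with the Leiden method at resolution 1.0, without integration of the libraries. Clusters were numbered from 0 and named from 11 lists of cell type markers by the class with the highest mean z-score, with at least 3 markers detected in at least 10% of cells. A cluster stayed unnamed where its median UMIs were under 1 part in 3 of the median of its library and its 10 leading genes held no marker of its class, a rule made precise after the clusters were seen. Germ-cell-like cells were those of clusters named for germ cells or primed pluripotent cells. Clusters 2 (unnamed) and 15 (red-blood-cell-like) were kept out of both classes. Somatic-like cells were those of the Leydig, Sertoli, endothelial, mesenchymal and white blood cell clusters.

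UMIs of the germ-cell-like cells were summed per library and scaled to a common total as CPM. Log2 ratios were RFP-negative over RFP-positive, each with an exact conditional binomial 95% interval. With 1 library per group no test of the groups was possible and no p-value was computed, and all intervals cover counting error only. Genes were counted by size alone, as at least 2-fold higher or lower among genes at 20 CPM or more in at least 1 library. A gene with 0 UMIs in 1 library was taken as a bound at 3 UMIs. The 23 fixed gene lists covered male germ cell differentiation, core and naive pluripotency, primed pluripotency, NODAL, FGF, BMP and WNT signalling, MYC, cell cycle (S phase, G2 and M phase, G1 cyclins and inhibitors), metabolism (glycolysis, nuclear and mitochondrial oxidative phosphorylation genes), DNA methylation, imprinting, p53, teratoma susceptibility, primordial germ cells, spermatogonia, meiosis, immediate-early genes, and Y-linked genes with Xist. List members at 5 CPM or more in at least 1 library counted as measured. Each list was described by the members at least 1.5-fold higher or lower, its median log2 ratio, and the percentile of that median among 10000 random lists of the same size matched on mean CPM in 20 bins. A percentile describes these libraries only.

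Genes named for their ratio were 13 fixed genes (Nanos2, Dnmt3l, Pou5f1, Sox2, Nanog, T, Nodal, Lefty1, Otx2, Stra8, Ccnd1, Mki67 and Cdkn1b), up to 4 measured members per list with the largest absolute log2 ratio, and the 10 highest and 10 lowest ratios outside the lists at 20 CPM or more, without gene models that lack a symbol and without mitochondrially encoded genes. Any other gene named was chosen after its values were seen.

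Shares of cells with a UMI of 18 fixed genes were taken after random thinning of each cell to 3000 UMIs, with shallower cells left out and exact (Clopper-Pearson) 95% intervals. Somatic-like cells of the same library served as the background, in which doublets with germ cells were not excluded. Cell cycle phases were called with scanpy from the S phase and G2 and M phase lists on the thinned cells. RFP-negative germ-cell-like cells were clustered again by the same settings at resolution 0.5, numbered by size from 1, and described by CPM with exact Poisson 95% intervals.

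Alternatives covered a median log2 ratio set to 0, TMM factors from edgeR 4.0.16 in R 4.3.3, a mean over cells of each cell's CPM, totals without genes above 1% of UMIs, all cells passing the filter, no filter, at least 2000 detected genes, doublets kept, 10% of each sum subtracted in the profile of barcodes with 1 to 100 UMIs, minimums of 10 and 50 CPM, a 1.5-fold threshold, resolutions of 0.5 and 2.0, a cell-by-cell germ cell call, and thinning to 1500 or 6000 UMIs or none. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

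The ratios were tested on simulated Poisson counts drawn from 1 profile, the mean of both sums, with set folds for some genes. No spread between cells, mice or libraries was simulated, so the rates cover counting error and not differences between libraries. The 95% intervals held the true ratio in 94.7% of 4925 genes, and 0 of 4725 unchanged genes were counted as 2-fold. Of 50 genes simulated at each true fold, 0 were counted at 1.5-fold, 27 at 2-fold, 50 at 3-fold and 50 at 4-fold. Of 200 unchanged lists of 15 genes, 2.5% lay outside the central 95% of random lists. Pseudotime and isoforms were left out, since 1 library per group and UMI counts per gene give no test of either.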

Results

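Germ cells of E15.5 embryos, the stage at which male germ cells stop dividing and take up the male program, were compared by whether they carried the NANOS2-RFP reporter. NANOS2 is an RNA-binding protein that male germ cells use for this switch, and the strain is prone to testicular teratomas, tumors that arise from germ cells. The RFP-positive library held 17589 called barcodes with 197804823 UMIs, a median of 11151 UMIs (500 to 52303) and 2914 genes per barcode. The RFP-negative library held 3141 called barcodes with 96191198 UMIs, a median of 32063 UMIs (501 to 125975) and 5186 genes per barcode. Called barcodes took 92.5% of UMIs in the RFP-positive and 92.4% in the RFP-negative library. Each group had 1 library and no replicate, so differences are given by size, and intervals cover counting error only. The filter passed 14666 RFP-positive and 2413 RFP-negative cells.

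Germ-cell-like cells made up most of both libraries, with 13172 RFP-positive cells (89.8%, exact 95% interval 89.3 to 90.3) and 1977 RFP-negative cells (81.9%, 80.3 to 83.4). Most RFP-positive germ-cell-like cells lay in clusters 3, 4, 5, 7 and 10, and most RFP-negative ones in clusters 8, 9 and 12. Cluster 9 held 958 RFP-negative and 302 RFP-positive cells, cluster 8 held 498 and 377, and cluster 12 held 300 and 37. Clusters 3, 4, 5 and 7 held 2749, 2828, 2160 and 1551 RFP-positive cells against 5, 5, 1 and 4 RFP-negative ones, and cluster 10 held 2242 against 100. With 1 library per group, a cluster taken mostly from 1 library cannot be separated from that library. By highest marker score, clusters 8, 9 and 12 were nearest to primed pluripotent cells, the epiblast-like state that uses Otx2, Fgf5 and Lefty1, and together they held 1756 RFP-negative cells (72.8%, 70.9 to 74.5) and 716 RFP-positive cells (4.88%, 4.54 to 5.24). Cluster 12 alone had all 11 primed markers detected, with a mean z-score of 3.29 against 0.70 in cluster 8 and 0.59 in cluster 9, and clusters 8 and 9 are therefore given by number. Cell cycle genes were among the leading genes of clusters 8 (Nusap1, Ube2c, Top2a and Mki67) and 12 (Hist1h1b and Mki67). In the 37 RFP-positive cells of cluster 12, Lefty1 was at 8.35 CPM against 221 CPM in the RFP-negative cells of that cluster, and Fgf5 had 0 UMIs (upper limit 6.16 CPM) against 16.6 CPM. Pou3f1 was at 20 CPM (10.4 to 35.0) in the 37 cells against 30.2 CPM, and Otx2 at 26.7 CPM (15.3 to 43.4) against 96.6 CPM, with 7.99 and 10.3 CPM in all RFP-positive germ-cell-like cells. Lefty1 (2.71 to 19.5 in the 37 cells) was at 0.841 CPM and Fgf5 at 0.398 CPM in that sum. Otx2, Pou3f1 and Lefty1 thus lay above the level of the library, as did Eomes at 8.35 CPM (2.71 to 19.5) against 2.66 CPM. Lefty1 and Eomes rested on 5 UMIs each in the 37 cells. The markers named this cluster, so their levels describe it and test nothing. The intervals of the other 7 primed markers, Fgf5 and Dnmt3b (48.4 CPM against 45.0 CPM) among them, held the level of the library.

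Somatic-like cells were a small part of both libraries, 760 RFP-positive and 348 RFP-negative cells. Mesenchymal-like cells made up 3.75% (3.45 to 4.07) of RFP-positive and 9.95% (8.78 to 11.2) of RFP-negative cells. Sertoli-like cells, the supporting cells of the testis cords, made up 0.941% (0.791 to 1.11) and 2.98% (2.34 to 3.74). Endothelial-like cells made up 0.205% and 0.995%, Leydig-like cells 0.184% and 0.249%, and macrophage-like cells 0.102% and 0.249%. Cells without the reporter fall in the RFP-negative gate, so the sort itself can set these shares, as can the difference in depth. An unnamed cluster of low UMIs, cluster 2, held 4.60% and 3.48% of cells, and cluster 15, which combined hemoglobin genes with all 10 germ cell markers, held 60 and 4 cells.

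As shares of all UMIs, RFP-negative germ-cell-like cells had more NODAL pathway, pluripotency and cell cycle RNA and less RNA of male germ cell genes than RFP-positive ones. Amounts per cell were not compared. Lefty1, a NODAL target, was 99.8-fold higher in the RFP-negative sum, and Dnmt3l, a cofactor of new DNA methylation in male germ cells, was 6.39-fold higher in the RFP-positive sum. The Lefty1 fold rests on an RFP-positive level near the floor, at 0.841 CPM. Nanos2 itself was 1.53-fold higher in the RFP-positive sum. Of 5387 genes at 20 CPM or more, 433 (8.04%) were at least 2-fold higher and 212 (3.94%) at least 2-fold lower in the RFP-negative sum, and 44 and 50 of them passed 4-fold. These sums rested on 180750293 RFP-positive and 85694285 RFP-negative UMIs, with medians of 12277.5 and 41152 UMIs per cell. The median log2 ratio over these genes was 0.13, and with it set to 0 the counts were 304 higher and 282 lower, so the share of higher genes among both moved from 67.1% to 51.9% with the scaling. Without clusters 8 and 12 the counts were 247 and 171, and among cells of 10000 to 20000 UMIs, with 71 RFP-negative cells, they were 1065 and 263.

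Male germ cell genes were lower as a group in the RFP-negative sum. Of 18 measured members of the male differentiation list, 15 were at least 1.5-fold lower and 1, Elavl2, at least 1.5-fold higher, with a median log2 ratio of -1.36 (percentile 0 of random lists). Genes of the piRNA pathway, which silences transposons in male germ cells, had log2 ratios of -3.49 for Tdrd9 (56.1 CPM in RFP-positive and 5.01 CPM in RFP-negative cells), -2.76 for Piwil4 (79.0 and 11.7 CPM) and -2.65 for Tdrd1 (103 and 16.4 CPM). Dnmt3l (ENSMUSG00000000730, mm10 chromosome 10, 78041947 to 78063622) was at 71.0 CPM in RFP-positive and 11.1 CPM in RFP-negative cells, a log2 ratio of -2.67 (95% interval -2.77 to -2.58). Nanos2 (ENSMUSG00000051965, chromosome 7, 18987400 to 18988962) was at 77.6 and 50.6 CPM, a log2 ratio of -0.62 (-0.67 to -0.57), and 14 of the other 17 members had lower ratios. Without clusters 8 and 12 the Nanos2 ratio was -0.15, and without cells holding a UMI of a mitosis gene it was -0.18. The sort was made on a reporter of this gene, so its ratio is not independent of the grouping. The 10 germ cell markers had a median of -0.81, with 6 members lower and 2 higher, and a percentile of 0. Ddx4, Mael, Piwil2 and Tdrd1 among them are also in the male list, and the markers served to name clusters, so they add no separate support.

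Pluripotency genes were higher in the RFP-negative sum, most of all those of the primed state and of NODAL, the signal that keeps epiblast cells primed. NODAL list members were at least 1.5-fold higher in 7 of 10 cases and lower in 0, with a median log2 ratio of 1.5 (percentile 100). Lefty1 (ENSMUSG00000038793, chromosome 1, 180935022 to 180938400) was at 0.841 CPM in RFP-positive and 83.9 CPM in RFP-negative cells, a log2 ratio of 6.64 (6.41 to 6.88). Its neighbour Lefty2 had a ratio of 4.8, the NODAL co-receptor gene Tdgf1 4.87, and Nodal itself 1.64 (1.51 to 1.77). In the RFP-positive sum Lefty1, Lefty2 and Tdgf1 were near the floor, at 0.841, 0.990 and 0.454 CPM. Barcodes with 1 to 100 UMIs of that library held them at 2.43, 1.56 and 0.521 CPM, so the size of their ratios is uncertain. Primed pluripotency members were higher in 7 of 8 cases and lower in 0, with a median of 1.49 (percentile 100). Among them were Otx2 (10.3 and 52.5 CPM, ratio 2.35), Lhx1 (5.42 and 41.3 CPM, ratio 2.93) and Eomes at 2.25, while Sox11 was lower by less than 1.5-fold. T, which marks early mesoderm, was near the floor at 0.918 and 1.63 CPM, with a ratio of 0.83 (0.50 to 1.16) that was 0.23 without clusters 8 and 12. The 7 measured primed markers were all higher, with a median of 2.25 (percentile 100). They are also in the primed or the NODAL list and served to name clusters, so they add no separate support.

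Core and naive pluripotency members were higher in 10 of 19 cases and lower in 3, with a median of 0.70 (percentile 99.99). Pou5f1 (326 and 488 CPM) had a log2 ratio of 0.58 (0.56 to 0.60), Sox2 (49.4 and 102 CPM) 1.04 (1.0 to 1.08) and Nanog (6.49 and 21.9 CPM) 1.75 (1.65 to 1.86). The largest ratios of this list were 2.08 for Klf2, 1.75 for Nanog, 1.68 for Gdf3 and 1.52 for Klf5. Dppa4, Klf4 and Tfcp2l1, chosen after their values were seen as the lower members, had ratios of -0.76, -0.79 and -0.78. Among cells of 10000 to 20000 UMIs the list median was 0.39, against 0.30 over all genes at 20 CPM in that setting. Primordial germ cell genes did not move as a group, with 3 of 12 members higher, 2 lower and a median of 0.19 (percentile 76.6), with ratios of 2.24 for Kit, 1.63 for Prdm1, 0.75 for Dazl and -1.36 for Nanos3.

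**Figure D1:**
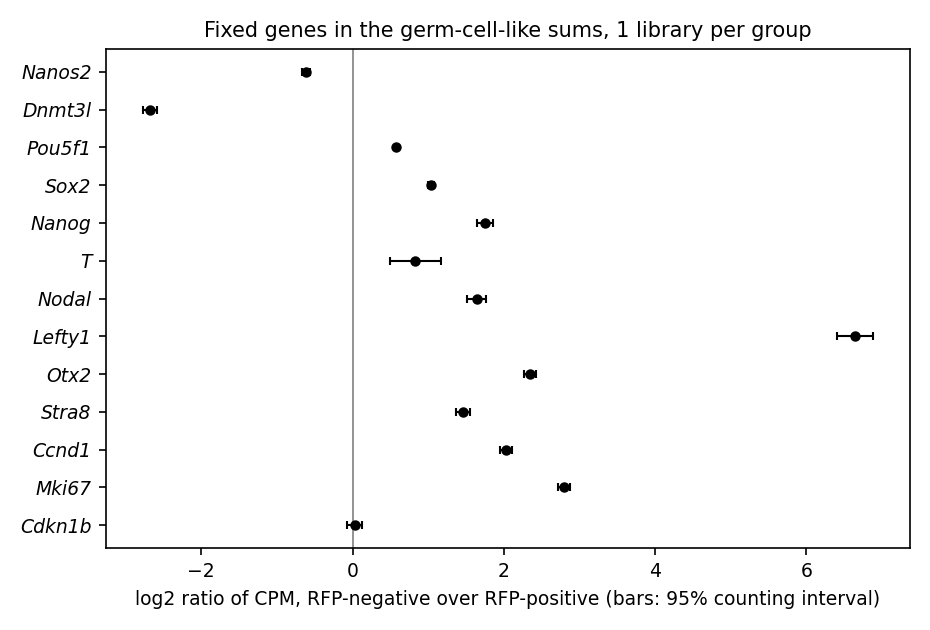
Log2 ratio of CPM, RFP-negative over RFP-positive, of the 13 fixed genes in the germ-cell-like sums of 1 library per group, as points with 95% counting intervals as bars. Nanos2 and Dnmt3l lie below 0, Cdkn1b has an interval across 0, and the other genes lie above 0, with Lefty1 at 6.64.

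Genes that respond to other growth factor signals were higher in the RFP-negative sum as well, while WNT lay within the range of random lists. FGF and ERK response members were higher in 8 of 10 cases and lower in 1, with a median of 1.22 (percentile 99.99) and ratios of 2.90 for Etv1, 2.32 for Dusp4, 2.26 for Dusp6 and 1.69 for Fgfr2. The FGF median was 0.84 without clusters 8 and 12, with 6 of 9 members higher and 2 lower. It was 0.79 without cells holding a UMI of a mitosis gene and 1.54 among cells of 10000 to 20000 UMIs. BMP response members were higher in 6 of 8 cases and lower in 0, with a median of 1.05 (percentile 100) and ratios of 4.21 for Id3, 1.81 for Id1, 1.19 for Smad7 and 1.07 for Bmp4. Id3 was at 148 and 358 CPM in the somatic-like cells of the RFP-positive and RFP-negative libraries, above its 1.46 and 27.1 CPM in germ-cell-like cells. WNT response members were higher in 3 of 7 cases and lower in 0, with a median of 0.31 (percentile 72.4) and ratios of 1.92 for Wnt3, 1.22 for Sp5 and 0.31 for Znrf3. The WNT median moved with the members measured, to 1.21 with 5 of 9 higher over all cells passing the filter, 0.89 with 5 of 8 higher among cells of 10000 to 20000 UMIs, and 1.01 with 2 of 4 higher at 20 CPM.

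Imprinted genes differed in both directions, with 12 of 20 members higher, 7 lower and a median of 0.86 (percentile 100). Log2 ratios were 2.58 for Mest, 2.52 for Gnas, 2.45 for Snrpn and -3.68 for Peg10. Mest and Gnas were abundant in somatic-like cells, at 359 and 1453 CPM in the RFP-negative library. DNA methylation genes split as well, with 6 of 12 members higher, 4 lower, a median of 0.32 (percentile 86.7) and a mean of -0.04 of the opposite sign. Without clusters 8 and 12 they were 2 higher and 4 lower with a median of 0.11. Tet1, which oxidizes methylated cytosine, was at 43.8 CPM in RFP-positive and 153 CPM in RFP-negative cells, Uhrf1, which maintains methylation, had a ratio of 1.39, and Morc1, which silences transposons, one of -1.64. Genes linked to mouse testicular teratoma were higher in 6 of 12 cases and lower in 1, with a median of 0.63 (percentile 99.4), with ratios of 2.24 for Kit, 2.09 for Ago2, 2.03 for Ccnd1 and 1.59 for Trp53. Kit was low in both sums, at 1.65 and 7.83 CPM.

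**Figure D2:**
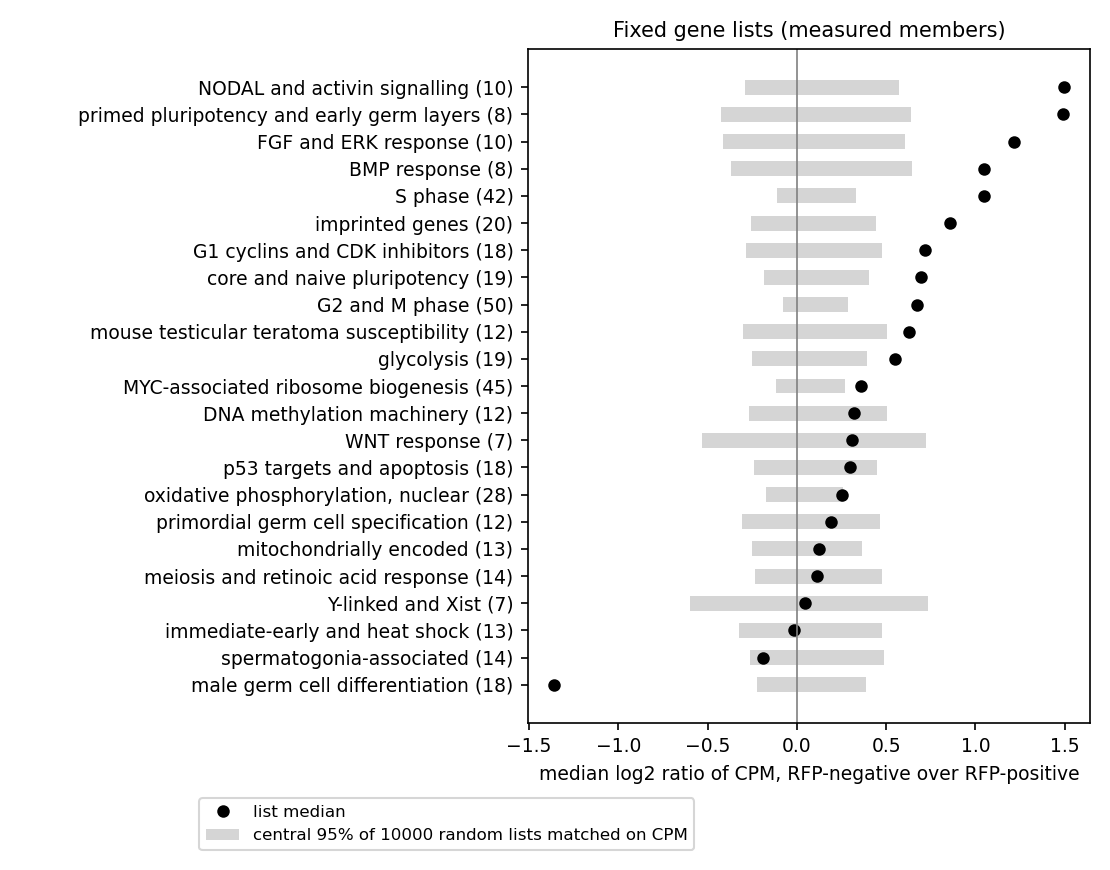
Median log2 ratio of CPM, RFP-negative over RFP-positive, of the measured members of each of the 23 fixed gene lists (points, number of members in brackets), with the central 95% of 10000 random lists as grey bars. Male germ cell differentiation lies below its bar at -1.36 and NODAL and activin signalling lies above its bar at 1.5.

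Cell cycle genes were higher in the RFP-negative sum. S phase members were higher in 29 of 42 cases and lower in 0 (median 1.05, percentile 100), and G2 and M phase members were higher in 31 of 50 cases and lower in 0 (median 0.67, percentile 100). Mki67, a marker of dividing cells (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), was at 8.67 CPM in RFP-positive and 60.1 CPM in RFP-negative cells, a log2 ratio of 2.79 (2.71 to 2.87), and Cdk1 and Ube2c had ratios of 2.21 and 2.05. In S phase, Rrm2 had a ratio of 3.25, Gmnn 1.84, Mcm2 1.69 and Exo1 1.67. G1 cyclins and inhibitors were higher in 10 of 18 cases and lower in 0 (median 0.72, percentile 99.9), with ratios of 3.22 for Ccne1, 2.03 (1.94 to 2.11) for Ccnd1, 1.19 for E2f3 and 1.14 for Ccne2. The inhibitor gene Cdkn1b was at 13.3 and 13.6 CPM, a ratio of 0.03 (-0.08 to 0.13) that was -0.10 with the median set to 0. These lists were lower without clusters 8 and 12, with medians of 0.42 for S phase and 0.15 for G2 and M phase. G1 members were then higher in 5 of 15 cases (median 0.46). The Mki67 ratio was 0.86 and that of Nusap1 -0.01, against 2.18 for Nusap1 with all cells. Leading genes of cluster 8 included Nusap1, Ube2c, Top2a and Mki67, and those of cluster 12 Hist1h1b and Mki67. The drop thus follows in part from the choice of cells.

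Phase calls put 91.2% (90.7 to 91.7) of RFP-positive and 95.8% (94.8 to 96.6) of RFP-negative germ-cell-like cells in S or G2 and M phase. Mki67 had a UMI in 2.23% and 12.4% of the same thinned cells. The calls reached 99.2% and 99.8% without thinning and 83.4% and 90.7% at 1500 UMIs, and 27.1% and 13.7% of cells lay near the boundary between phases. List members such as Cenpf and Tubb4b, chosen after their values were seen, were abundant in RFP-positive cells, at 576 and 601 CPM. Cycling was therefore not read from these calls.

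MYC-associated genes were higher in the RFP-negative sum by smaller amounts, and the direction of glycolysis genes depended on the cells taken. Of 45 MYC-associated members, which serve ribosome assembly and growth, 17 were higher and 1 lower, with a median of 0.36 (percentile 99.8). Mycn had a ratio of 1.90, Mycl 1.84, Hspd1 (338 and 1035 CPM) 1.61 and Odc1 1.46. The MYC median was 0.20 among cells of 10000 to 20000 UMIs, below the 0.30 over all genes at 20 CPM in that setting. Glycolysis members were higher in 8 of 19 cases and lower in 3, with a median of 0.55 (percentile 99.8) and ratios of 3.15 for the lactate exporter gene Slc16a3, 1.98 for Tpi1, 1.85 for Ldhb and -1.45 for Aldoc. Among cells of 10000 to 20000 UMIs 4 of 18 glycolysis members were higher and 7 lower, with a median of 0.10. Nuclear oxidative phosphorylation members were higher in 8 of 28 cases and lower in 2, with a median of 0.26 (percentile 97.2) and ratios of 1.52 for Ndufa1, 0.79 for Ndufb8 and 0.78 for Uqcrc2. The 13 mitochondrially encoded genes had 0 members beyond 1.5-fold and a median of 0.12 (percentile 75.3) that was -0.01 with the median of all genes set to 0, with ratios of 0.54 for mt-Nd6, 0.33 for mt-Nd1, 0.29 for mt-Cytb and -0.28 for mt-Atp8.

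Other lists showed no common direction over all germ-cell-like cells, though the meiosis and p53 lists did among cells of 10000 to 20000 UMIs. Spermatogonia-associated genes were higher in 5 of 14 cases and lower in 6, with a median of -0.19 (percentile 5.51) and a mean of 0.09 of the opposite sign. In this list Sohlh1, which starts spermatogonial differentiation, had a ratio of -3.14, its partner Sohlh2 2.90, and Lhx1 2.93. Meiosis genes were higher in 4 of 14 cases and lower in 3, with a median of 0.11 (percentile 48.9) that was -0.02 with the median of all genes set to 0. Stra8, the gene that opens meiosis in response to retinoic acid, was at 10.1 and 27.8 CPM with a ratio of 1.46 (1.37 to 1.55), Syce2 had 0.87, Syce3 -1.57 and Tex12 -1.35. Among cells of 10000 to 20000 UMIs, with 71 RFP-negative cells, 15 of 18 meiosis members were higher and 0 lower, with a median of 1.75, and the ratios of Syce3 and Tex12 turned positive. The p53 and apoptosis list had 7 of 18 members higher, 2 lower and a median of 0.30 (percentile 86.0), with ratios of 1.59 for Trp53, 1.30 for Pmaip1, -0.98 for Casp9 and -0.89 for Bcl2l1. This list had 13 of 18 members higher and a median of 1.29 among cells of 10000 to 20000 UMIs, and 3 of 17 higher and 3 lower without clusters 8 and 12.

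Immediate-early and heat shock genes, which can respond to cell dissociation, were higher in 2 of 13 cases and lower in 4, with a median of -0.02 (percentile 33.1) that was 0.02 with TMM factors and 0.33 over all cells passing the filter. Ier2 had a ratio of 3.28, Ddit3 -1.38, Jun -1.01 and Ier3 -0.87, and the ratio of Jun turned to 0.40 over all cells passing the filter. Jun was at 306 and 429 CPM in somatic-like cells against 14.3 and 7.12 CPM in germ-cell-like cells. Y-linked genes and Xist were near equal, with 0 of 7 higher, 1 lower and a median of 0.05 (percentile 46.1) that was -0.12 with the median of all genes set to 0, and a mean of -0.38. The lower member was Usp9y (12.5 and 1.04 CPM, ratio -3.59), which has a close copy on the X chromosome, while Kdm5d, Ddx3y and Zfy1 had ratios of 0.43, 0.34 and 0.32.

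Outside the lists, the lowest ratios included further genes of the male germ line. Spocd1, a partner of piRNA-directed DNA methylation (ENSMUSG00000028784, chromosome 4, 129929249 to 129957115), was at 25.3 CPM in RFP-positive and 0.689 CPM in RFP-negative cells, a log2 ratio of -5.20 (-5.59 to -4.83). It was followed by ratios of -4.37 for Syce1l, -4.13 for Drc1, -4.12 for Slc38a4, -3.99 for Mt1, -3.55 for Ifi27l2a, -3.55 for Fxyd1, -3.47 for Lrrc27, -3.25 for Dpep3 and -3.25 for the X-linked gene Nxf2, which was at 375 and 39.4 CPM. The highest ratio was 4.75 for Hist1h1b, a linker histone gene used in S phase (4.48 and 120 CPM), and Hist1h1e had 3.32. L1td1, an RNA-binding protein gene of pluripotent cells, had a ratio of 4.59 (3.89 and 93.4 CPM), and Khdc3, known from oocytes and early embryos, one of 4.12. The others were 3.54 for Trh, 3.45 for Txn1, 3.05 for Ckb, 2.87 for Glrx, 2.82 for Tdh and 2.73 for Mdk.

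Shares of cells gave the same order as the sums for 17 of 18 fixed genes, Cdkn1b being the exception, once each cell was thinned to 3000 UMIs, which left 13132 RFP-positive and 1963 RFP-negative germ-cell-like cells. Nanos2 had a UMI in 20.3% (19.6 to 21) of RFP-positive and 14.7% (13.2 to 16.4) of RFP-negative germ-cell-like cells, against 7.0% (4.84 to 9.74) and 1.0% (0.207 to 2.89) of somatic-like cells. Dnmt3l had one in 18.2% and 2.90%, against 5.91% and 0% (upper limit 1.22) of somatic-like cells. Ddx4, a general germ cell gene, had one in 60.2% and 37.9%, and Dazl in 69.4% and 85.9%, against 21.7% and 2.33%, and 30.4% and 5.33%, of somatic-like cells. Pou5f1 had one in 62.2% and 76.2% (somatic-like 22.5% and 4.33%), Sox2 in 13.1% and 25.8% (4.16% and 1.0%), Nanog in 1.78% and 6.21% (0.875%, upper limit 2.23, and 0%) and Dppa5a in 80.3% and 97.2% (31.3% and 10.3%). Thinning left out 303 of 760 RFP-positive and 48 of 348 RFP-negative somatic-like cells. The RFP-positive background rose steeply with the depth asked for, with Pou5f1 in 8.68% of 726 cells at 1500 UMIs and 67.2% of 195 cells at 6000 UMIs, and Nanos2 in 1.93% and 26.7%. In RFP-negative somatic-like cells the Pou5f1 shares were 0.935% and 7.22%. The median depths before thinning were 12277.5 and 41152 UMIs for germ-cell-like cells and 3449 and 10000.5 UMIs for somatic-like cells.

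NODAL pathway genes had a UMI in a larger share of RFP-negative than of RFP-positive germ-cell-like cells. Lefty1 had one in 0.145% (0.0871 to 0.226) of RFP-positive and 15.3% (13.7 to 17.0) of RFP-negative cells, against 0.656% and 0.333% of somatic-like cells, so the RFP-positive share was at background. Lefty2 had one in 0.267% (0.186 to 0.370) and 7.54%, against 2.19% (1.05 to 3.99) and 0.333% of somatic-like cells, so the RFP-positive share was below that of somatic-like cells. Nodal had one in 1.36% and 4.23% (0.219%, upper limit 1.21, and 0%), Otx2 in 2.79% and 12.6% (0.656% and 0%) and Stra8 in 2.60% and 4.79% (0.438% and 0.333%). T had one in 0.236% and 0.713%, with somatic-like shares of 0% (upper limit 0.804) and 0.333% whose intervals overlapped. Mki67 had a UMI in 2.23% and 12.4% of germ-cell-like cells and in 22.3% and 20.7% of somatic-like cells, which also divide. Ccnd1 had one in 2.81% and 9.68% (somatic-like 9.85% and 9.33%) and Cdkn1c in 24.1% and 39.2% (43.5% and 50.3%). For Cdkn1b the shares of 4.01% and 3.82% (8.97% and 6.67%) had overlapping intervals. Without thinning the Nanos2 shares were 59.9% and 73.4%, against the order of the sums, and no order was read from them because RFP-negative cells were deeper.

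**Figure D3:**
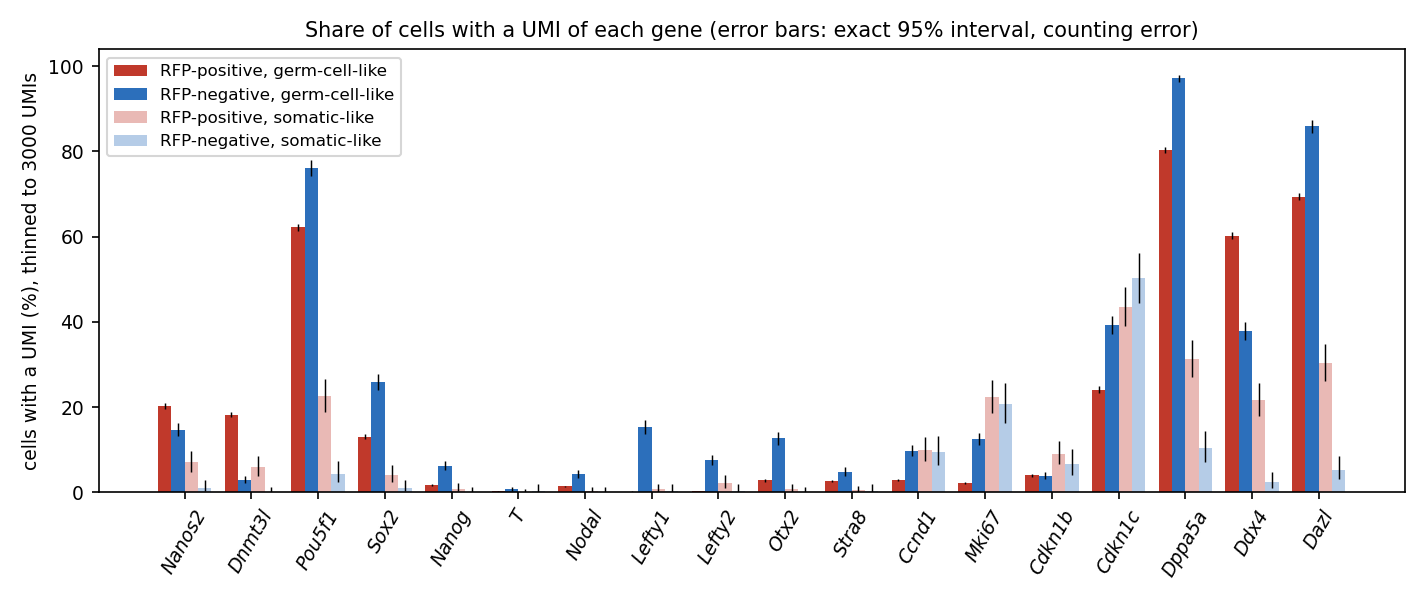
Percent of cells with a UMI of each of 18 fixed genes after thinning to 3000 UMIs per cell, for germ-cell-like (dark bars) and somatic-like cells (pale bars) of the RFP-positive and RFP-negative library, with exact 95% intervals. Lefty1 stands at 0.145% and 15.3% in germ-cell-like cells, and Dnmt3l at 18.2% and 2.90%.

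RFP-negative germ-cell-like cells were not uniform, and they formed 8 clusters of 640, 398, 291, 211, 145, 138, 86 and 68 cells when grouped alone. Genes that set such clusters apart define them, so their levels describe the clusters and test nothing. Nanos2 was at 84.8 CPM in cluster 1 and 89.8 CPM in cluster 8, above the 77.6 CPM of the RFP-positive sum, and at 13.8 CPM in cluster 6. Cluster 8 also had Piwil4 at 59.4 CPM, Dnmt3l at 41.4 CPM and 13 of 18 male differentiation members higher than in the rest, with a median log2 ratio of 1.01. Cluster 1 had 9 of these members higher and a median of 0.59, with Dnmt3l at 8.24 CPM. Mki67 was at 6.2 CPM in cluster 1 and 4.92 CPM in cluster 8, against 201 CPM in cluster 5, 113 CPM in cluster 6 and 105 CPM in cluster 2. Cluster 5 had 39 of 42 S phase members higher than in the rest (median 1.36), and cluster 2 had 32 of 49 G2 and M phase members higher (median 0.77).

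Cluster 6, most of which lay in cluster 12 of the joint grouping, carried Lefty1 and Otx2 at their highest levels among these 8 clusters. Lefty1 was at 327 CPM and Otx2 at 151 CPM there, against 134 CPM (cluster 3) and 74.8 CPM (cluster 4) in the next highest. Its median log2 ratio over the rest was 1.88 for the primed list, 1.47 for the NODAL list, 1.03 for glycolysis and -1.55 for male differentiation. Dnmt3l was at 44.1 CPM in cluster 6, near its level in cluster 8, while Piwil4 was at 3.03 CPM there and Ddx4 at 45.3 CPM. Cluster 7 stood apart by Stra8, at 445 CPM (422 to 470) against 45.5 CPM in the next highest cluster. All 14 measured meiosis members were higher in cluster 7, with a median of 2.67, and the naive pluripotency list had a median of -1.30.

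**Figure D4:**
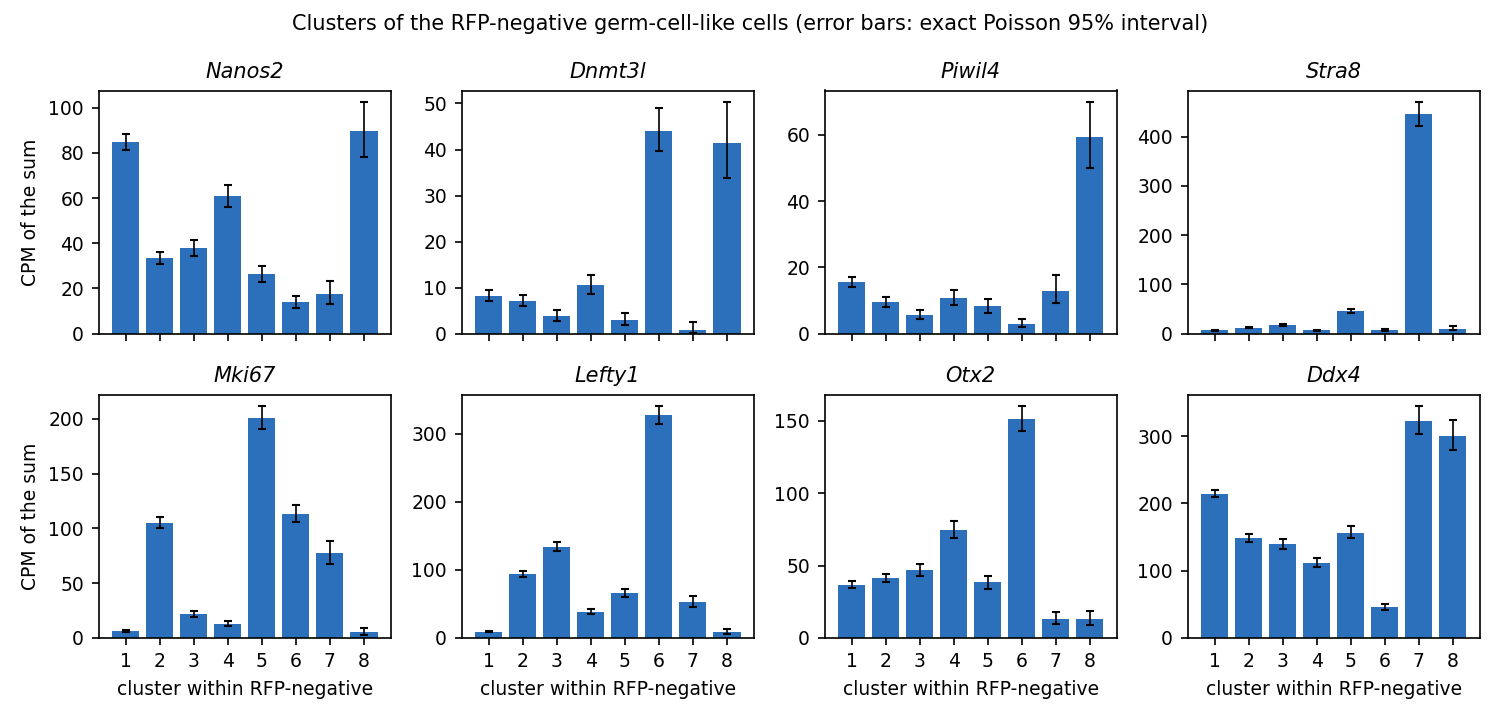
CPM of Nanos2, Dnmt3l, Piwil4, Stra8, Mki67, Lefty1, Otx2 and Ddx4 in the sums of the 8 clusters formed by RFP-negative germ-cell-like cells alone, as bars with exact Poisson 95% intervals. Stra8 peaks in cluster 7 at 445 CPM, Lefty1 in cluster 6 at 327 CPM and Piwil4 in cluster 8 at 59.4 CPM.

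Mesenchymal and Sertoli markers were mostly near 0 in the germ-cell-like sums, and germ cell RNA was found in somatic-like cells. Clusters named by these somatic markers had been left out of the germ-cell-like sums. The mesenchymal gene Dcn was at 0.144 CPM in RFP-positive and 0.128 CPM in RFP-negative germ-cell-like cells, against 331 and 557 CPM in somatic-like cells. Col1a2 was at 0.172 and 0.128 CPM, and the Sertoli gene Amh at 0.813 and 0.630 CPM against 309 and 520 CPM. Of the marker lists of other cell types, 1 Leydig, 1 endothelial, 1 mesenchymal, 2 mesonephric, 1 ovarian support and 1 red blood cell gene reached 5 CPM in a germ-cell-like sum, and 0 Sertoli, macrophage or peritubular myoid genes did. The highest of these, Epcam, was at 49.4 and 200.5 CPM, against 31.1 and 49.2 CPM in somatic-like cells, followed by Egfl7 at 31.2 and 19.5 CPM and Rspo1 at 19.6 and 20.1 CPM. Pou5f1 was at 156 CPM in RFP-positive and 55.9 CPM in RFP-negative somatic-like cells, and Nanos2 at 41.0 and 6.23 CPM. In the RFP-positive library this RNA lay mostly in the deeper somatic-like barcodes, with Dppa5a and Dazl in 76.4% and 75.9% of the 195 cells at 6000 UMIs, against 28.0% and 29.1% of all 760 cells without thinning. Such barcodes may be doublets of germ and somatic cells, which the caller did not detect, so the sums do not give a level of germ cell RNA outside germ cells.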

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

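The tests on somatic RNA, on dividing cells, on free RNA and mis-sorted cells behind Nanos2, and the free RNA test used for cluster 12 were chosen only after related results had been seen.

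Barcodes with 1 to 100 UMIs, used only as a profile of free RNA, held the hemoglobin gene Hbb-bs at 2271 CPM in the RFP-positive and 1772 CPM in the RFP-negative library, above the limit that a count of 0 allows. Barcodes failing the filter, with median mitochondrial shares of 18.1% and 28.9%, held Pou5f1 at 235 CPM and 302.4 CPM, again above that limit. The unnamed cluster 2 held 4.596% of RFP-positive and 3.481% of RFP-negative cells, with median UMIs of 3065.5 and 6598.5, and entered only the alternative settings that take them in.

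NODAL, primed, naive pluripotency and cell cycle lists were higher in RFP-negative germ-cell-like cells. Among cells of 10000 to 20000 UMIs 5 of 5 lists kept at least 50% of their median, although only 71 RFP-negative cells against 8614 entered. This argues against depth alone for the NODAL, primed and cell cycle lists, within the cells taken. The comparison changed the mix of cells as well as depth, with a meiosis list median of 1.75 against 0.11 over all cells. The median over all genes at 20 CPM rose from 0.13 to 0.30 in that setting. Naive pluripotency kept 55.9%, a median of 0.39 that was near this value, so depth stays open for that list. RNA or cells of somatic type gave 0.223% of the excess in the median of 84 higher members, from marker shares of 0.454% in RFP-positive and 0.138% in RFP-negative sums. The mesenchymal and Sertoli markers used here also named clusters left out of these sums. For cells of somatic type a low share was thus in part set in advance. A larger share of dividing cells was examined in 2 clusters formed by RFP-negative cells alone with less Mki67 than the RFP-positive sum. These were clusters 1 and 8 with 708 cells, at 6.09 against 8.67 CPM. Over the RFP-positive sum they had medians of -0.0036 for S phase and 0.01 for G2 and M phase. Their medians were 0.70 (0.33 to 1.12) for naive pluripotency and 0.96 (0.42 to 2.06) for NODAL, 101% and 63.9% of the medians over all cells. Ranges are the central 95% of medians over members drawn with replacement. Dividing cells are thus argued against as the whole cause for these 2 lists within clusters 1 and 8 only. The clusters were formed on their own genes, with the naive member Tfcp2l1 among the leading genes of cluster 1, so nothing follows for all cells. For the primed list dividing cells cannot be told apart from other causes, since its median of 0.90 (-0.30 to 1.75), 60.6%, has a spread across 0. A part from dividing cells stays open for every list. A biological difference between cells with and without the reporter, and any other difference between the 2 libraries, stay open and untested, since each group has 1 library.

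Nanos2 RNA was present in RFP-negative germ-cell-like cells at 65.2% (63.0 to 67.5) of the RFP-positive level. Free RNA in that suspension is argued against, since Nanos2 in RFP-negative somatic-like cells was 12.3% (8.19 to 17.8) of the level in germ-cell-like cells. Mis-sorted cells of the RFP-positive kind are argued against as the whole cause, since the other 17 male differentiation members had a median of 37.8% of their RFP-positive level, with 14 of them below Nanos2. A part from such cells stays open, as does a lag between Nanos2 RNA and the reporter protein, which was not measured.

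The RFP-positive library had 37 cells in cluster 12, the cluster with the primed markers. Barcodes shared between the libraries are argued against, since 1 of the 37 (2.70%, 0.0684 to 14.2) carried a barcode that the RFP-negative library also called, of 324 called in both. Free RNA was set against their 74 UMIs (58.1 to 92.9) of 11 primed markers. These markers named cluster 12, with Lefty1 among its leading genes. Cells placed there are thus in part selected for such UMIs, which the intervals leave out. A sum made only of the RNA in barcodes with 1 to 100 UMIs would hold 60.8, but the share of free RNA in these cells was at most 65.2% by the male differentiation list and 34.3% by 66 markers of somatic cell types, and the higher limit gives at most 39.6 UMIs. Of the 74 UMIs 29 were of Dnmt3b, which was near its level in all RFP-positive germ-cell-like cells (48.4 against 45.0 CPM), and without it 45 UMIs (32.8 to 60.2) stand against at most 13.4. Mesenchymal markers alone limited the share of free RNA to 5.12%, or 3.11 primed UMIs. Red blood cell markers limited it to 0.77%, or 0.47 primed UMIs. Both marker sets also named other clusters, so low values were in part set in advance. As far as barcodes with 1 to 100 UMIs give its profile, free RNA is argued against as the whole source. A part from free RNA stays open. Doublets cannot be told apart from single cells here: the median doublet score lay at percentile 8.88 (6.40 to 14.5), which the bound written before this value was seen would read as against doublets, but the caller marked 0 of 14666 cells, so its score is not shown to find doublets. No biological explanation was tested for these cells, which had Mki67 at 195 CPM and Nanos2 at 46.8 CPM.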

How the results depend on the processing

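The settings that add the unnamed cluster, leave out the 10% highest doublet scores, leave out cells with a UMI of a mitosis gene, leave out clusters 8 and 12, or keep cells of 10000 to 20000 UMIs were chosen after seeing the data, as was the choice of Nanos2 and of the male, naive, primed, NODAL and MYC lists as main results. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The mitosis genes were Mki67, Top2a, Cdk1, Cenpf and Ube2c, and leaving out cells with a UMI of any took out 88.2% of RFP-positive and 93.0% of RFP-negative cells, so this cut does not sort dividing from resting cells. Keeping doublets changed nothing, since none had been removed, and says nothing about stability.

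In all settings run, more genes were 2-fold higher than lower in the RFP-negative sum, and no list median outside the central 95% of random lists changed sign, while medians near 0 (meiosis, immediate-early, spermatogonia-associated, mitochondrially encoded, and Y-linked genes) did in some. Of 368 list medians under these settings 223 stayed between the medians of their members' counting limits and 145 moved. Of 690 member counts 627 stayed within a factor of 1.5 and 63 left it. Of 1554 ratios of named genes 1070 stayed within their counting interval, 478 moved and 6 reversed. Of 108 shares of cells, all at other thinning depths that change shares by construction, 3 stayed. The limits cover counting error only. The first 3 totals include the setting that kept doublets, which equals the main one. The counts of 433 higher and 212 lower genes left a factor of 1.5 in these settings: 247 higher without clusters 8 and 12, 1065 higher among cells of 10000 to 20000 UMIs, 376 lower at 10 CPM, 210 higher and 90 lower at 50 CPM, and 1170 higher and 603 lower at 1.5-fold. The CPM and fold settings change the counts by construction, and for the others the cause was not tested.

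Higher MYC members numbered 11 without mitosis-gene cells, and lower ones 3 among cells of 10000 to 20000 UMIs. Among cells of 10000 to 20000 UMIs 15 of 18 meiosis and 13 of 18 p53 members were higher, and 4 of 18 glycolysis members were higher and 7 lower. At 20 CPM fewer members were measured, with 4 higher NODAL and 3 higher primed members. The count of higher male members, 1, was 0 with the median set to 0, over all cells, with ambient RNA subtracted, and without clusters 8 and 12. The count of lower primed members, 0, was 1 with the median set to 0, with ambient RNA subtracted, without mitosis-gene cells, without clusters 8 and 12, and among cells of 10000 to 20000 UMIs. The cause was not tested.

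The Nanos2 log2 ratio was -0.75 with the median set to 0, -0.54 as a mean over cells, -0.18 without mitosis-gene cells, -0.15 without clusters 8 and 12, and -0.49 among cells of 10000 to 20000 UMIs. Nusap1 reversed to -0.045 without mitosis-gene cells and -0.0090 without clusters 8 and 12, Jun to 0.40 over all cells, and Syce3 and Tex12 to 1.41 and 0.54 among cells of 10000 to 20000 UMIs. Jun reached 5.76 with ambient RNA subtracted, because the subtraction took it to 0 in RFP-positive cells. Nusap1 was a leading gene of cluster 8, so its drop without clusters 8 and 12 follows in part from the choice of cells. For the others the cause was not tested.

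Germ-cell-like cells made up 86.1% of RFP-positive and 71.8% of RFP-negative cells without a filter, 97.8% and 87.5% at 2000 detected genes, 95.3% and 85.6% cell by cell, 94.4% and 85.4% with the unnamed cluster, and 83.7% of RFP-negative cells at resolution 2.0. Depth limits shares and phase calls. Calls of S or G2 and M phase reached 83.4% and 90.7% at 1500 UMIs, 95.4% and 97.2% at 6000 UMIs, and 99.2% and 99.8% without thinning. Nanos2 shares were 11.1% and 7.45% at 1500 UMIs, 36.1% and 25.4% at 6000 UMIs, and 59.9% and 73.4% without thinning.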

Other observations

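The test on Y-linked genes was chosen only after the cells concerned had been seen, and the test on X-linked genes was set before its value was seen, apart from its reading when the value lies on the bound.

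Cells with early meiosis genes were found in both libraries, in cluster 6 of the joint grouping, with 413 RFP-positive and 69 RFP-negative cells. These genes help define the cluster, so their levels describe it, and the genes named were chosen after their values were seen. Stra8 was at 124 CPM in RFP-positive cells of the cluster against 6.24 CPM in the other RFP-positive germ-cell-like cells, and at 402 CPM against 18.0 CPM in the RFP-negative library. Sycp3, of the synaptonemal complex that pairs chromosomes, was at 222 against 146 CPM and at 1125 against 69.3 CPM. Of 14 meiosis members, 7 were at least 1.5-fold higher in RFP-positive cells of the cluster than in the rest (median log2 ratio 0.58) and 14 in RFP-negative ones (median 3.04). Pou5f1 was lower there, at 282 against 327 CPM and at 171 against 496 CPM, and the naive pluripotency list had medians of -0.37 and -1.42. Whether the libraries differ in this was not tested.

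Cells with p53 target genes formed cluster 11, with 482 RFP-positive and 16 RFP-negative cells, and were chosen and described after their values were seen. In RFP-positive cells of the cluster, Phlda3 was at 90.1 CPM against 3.39 CPM in the rest, the cell cycle inhibitor gene Cdkn1a at 83.0 against 18.6 CPM, Ccng1 at 87.1 against 14.1 CPM, and Bbc3, which promotes apoptosis, at 25.5 against 2.64 CPM. The p53 list had 9 of 18 members higher with a median of 0.58 in RFP-positive cells, and 12 of 18 with a median of 1.38 in RFP-negative ones. In the 16 RFP-negative cells the male differentiation list had a median of 1.03 over the rest and the G2 and M phase list one of -0.83.

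Cluster 15 held 60 RFP-positive and 4 RFP-negative cells with Hbb-bs at 52196 and 96297 CPM and Pou5f1 at 292 and 419 CPM.

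A hypothesis was that the Stra8-high cells of cluster 7 within the RFP-negative library may be female germ cells, which enter meiosis in the embryo. The summed level of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 151 CPM (138 to 166) in these 86 cells and 139 CPM in the other RFP-negative germ-cell-like cells, 109% (99.1 to 120), which argues against it. Xist was at 3.72 CPM from 11 UMIs there and 8.57 CPM in the others.

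A further hypothesis was that genes lower in RFP-negative cells may be enriched on the X chromosome. Of 212 genes at least 2-fold lower, 13 were X-linked (6.13%), on the upper bound of random sets matched on CPM (1.42 to 6.13, percentile 97.8), so the value decides nothing. Examples chosen after their values were seen were Nxf2, Mageb4 and Rhox10, with log2 ratios of -3.25, -2.14 and -2.06. Of 433 higher genes, 15 were X-linked (3.46%, percentile 56.0). Chromosome 19, which comes from MOLF/Ei in this strain, held 2.83% of the lower and 3.70% of the higher genes, at percentiles of 35.5 and 58.2 of random sets.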
